A study of Arabidopsis thaliana with 24 samples.

How the data were processed

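Gene expression was measured on Affymetrix ATH1 arrays in 24 samples of wild-type Arabidopsis thaliana. Per the labels' protocols, plants grew for 3 weeks in short days and then in long days. Stem fragments of 1.5 cm, taken 2.5 cm above the base, were placed on split plates with MS medium, with or without the synthetic auxin NAA, and after 2 or 5 days the central 3 mm that did not touch the medium were frozen. Sections of 5 µm were used for laser capture, and RNA was amplified in a pair of rounds and labelled with biotin. The labels call the 3 arrays of each of the 8 groups biological replicates, and how many plants a replicate holds is not given in the sources used here.

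The values used are those the authors deposited in a single table of the whole series. The submitters' processing notes name RMA and limma, without versions or settings. The deposited values, which range from 1.73 to 13.51, were taken as log2 expression, the scale that RMA gives; the base of the logarithm is not written in the table. No scanner files were used here. Amplification starts at the 3' end, and the 5' probe sets of the GAPDH control lay at 2.42 to 2.90 on all arrays, so transcripts are measured near their 3' ends. RMA with quantile normalization would give arrays of equal spread; the spread of the deposited values differs between arrays, and which step leaves this difference is not given in the sources used here.

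The table holds 22810 probe sets, of which 64 are Affymetrix controls; the other 22746 were tested. In the annotation used, 13513 of all probe sets name 1 gene, 503 several and 8730 none, so that a gene without a name here may still be measured. Names were updated through the gene table of assembly TAIR10.1, in which 13436 probe sets matched a locus, and 11933 keep a locus code as symbol. No gene was named from a probe set with several. For 146 genes with several probe sets the one with the highest mean over all arrays was used.

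Each comparison used limma 3.58.1 in R 4.3.3, with statmod 1.5.0: a linear model with 1 mean per group over all 24 arrays, contrasts between groups, and eBayes (prior degrees of freedom 2.55, residual 16). Every adjusted p is Benjamini-Hochberg over the probe sets within a comparison, every test is two-sided, and the threshold was 0.05 with no minimum fold. A fold is 2 to the power of the size of the log2 change, and its error is the model's SE. The 14 contrasts were auxin against medium at 2 and 5 days, each tissue pair at 0, 2 and 5 days, each treated group against its untreated tissue, cambium against 2 days on NAA, and the interaction of tissue and time at 2 and 5 days. Probe sets called in the same direction in all 3 comparisons that isolate the interfascicular region were counted, beside 20 simulations of unchanged groups and the overlap of independent lists.

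Gene lists were tested with limma's camera with a preset correlation of 0.01 where at least 5 members were measured, adjusted over all pairs of list and contrast, and again with an estimated correlation. No call over the 56 pairs of the fixed lists or the 210 of the added lists held with the estimated correlation. The annotation named only 59 of the 423 entries of the 20 fixed lists, and 4 of those lists could be tested: early auxin response, Aux/IAA repressors, photosynthesis and wall loosening. For the others counts of members are given. A further 18 lists with 734 entries, 376 of them measured, were written after this was seen and before any gene's value was looked at; 15 could be tested.

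The genes named in the text follow a rule: in each contrast the 6 largest rises and the 6 largest falls with an adjusted p under 0.05, a symbol and arrays of the compared groups that do not overlap; up to 4 members with the smallest p of each called list and of a set of listed lists; 12 genes of interest whatever their values, of which MOL1 and GH3.3 have a probe set with a name; and the 10 genes of the intersections with the largest smallest change. Genes named outside this rule were chosen after their values were seen: members of the added and low oxygen lists, and uncalled genes given for comparison. MOL1 was picked by the study from these same arrays.

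The groups, tests, fixed lists, naming rule and the other settings listed here were set before the data were examined. They were a fit of only the compared groups, the replicate number as a block, a filter on probe sets whose highest group mean lay under the median of all values, 3.09 (leaving 14941), cyclic loess, array weights, an intensity trend with a robust prior, a minimum of 2-fold, the GAPDH 3' excess as a covariate, the mean of a gene's probe sets in list tests, and leaving out each array in turn. Quantile normalization, a fit without the 3 narrow arrays, a block over the 6 arrays of the 2-day tissue comparison, and counts of list members with the GAPDH covariate were added after seeing the data. Replicate numbers were taken to pair groups where all 3 same-numbered pairs deviated together with a correlation over 0.1. This held for the starch sheath and the stem on NAA at 2 days (0.126, 0.507 and 0.327), and for the stem at 2 days with the cambium (0.114, 0.13 and 0.103), which no contrast compares.

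The model was tested on data simulated from these arrays with 200 probe sets changed. It recovered 50 to 65% of 2-fold and 82 to 94% of 4-fold changes in the comparisons of groups, and 40% and 32% of 2-fold and 79% and 67% of 4-fold changes in the interactions at 2 and 5 days, with 1 to 9 false calls. The list test called the 1 shifted list and 0 of 20 others. These shares may not hold for arrays of unequal weight (0.154 to 5.154).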

Results

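Messenger RNA of laser-captured cells from wild-type Arabidopsis thaliana stems was profiled on 24 Affymetrix ATH1 arrays, which fall into 8 groups of 3 biological replicates. The starch sheath, the cell layer that borders the vascular bundles and the regions between them, was captured from untreated stems, after 2 days on medium with the synthetic auxin NAA, and after 2 and 5 days on medium alone. After 5 days on NAA the captured tissue was the cambium that had formed between the bundles. The surrounding stem tissue, without starch sheath and bundles, was captured untreated and after 2 and 5 days on NAA. The study sought genes that rise in the interfascicular region alone while auxin induces this cambium.

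The arrays differed in how widely their values spread. The SD over probe sets ran from 0.96 to 1.08 on 3 untreated arrays, replicates 2 and 3 of the starch sheath and replicate 3 of the surrounding stem, and from 1.22 to 1.57 on the other 21. These 3 narrow arrays held 532 to 836 probe sets above a log2 value of 6, against 1233 to 2255 on the others. Replicates correlated at 0.763 to 0.877 in the untreated starch sheath, 0.852 to 0.917 in the untreated surrounding stem and 0.917 to 0.972 in the remaining groups. The GAPDH control signal at the 3' end exceeded that at the 5' end by 3.93 to 5.50 on the log2 scale in untreated tissue and by 5.52 to 7.43 in cultured tissue. The 5' signal lay at 2.42 to 2.90 on all arrays, so this excess follows the 3' level (correlation 0.995) and is not by itself a measure of RNA quality; it is the GAPDH covariate below. No detection call was used, so a level is not known to lie above background. In 66 of 200 named calls between groups the lower group lies under 3.09, the median of all values, and a fold there is a ratio of fitted values and not a measured ratio of RNA. The 3 arrays in each group limit the precision of every value below, and the p-values measure only the spread between these replicates.

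**Figure D1:**
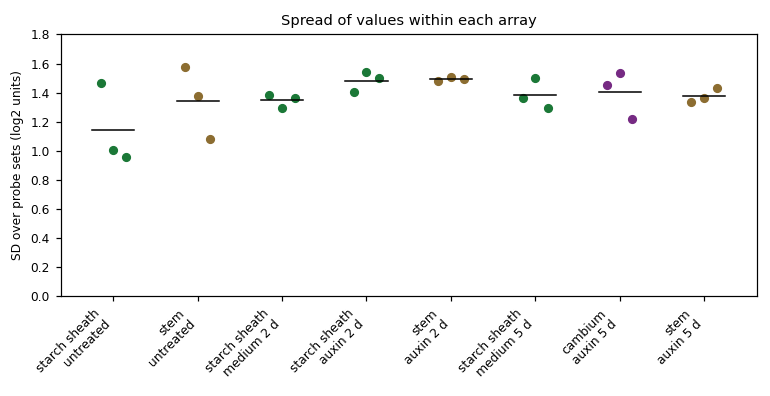
SD of the log2 values over the 22746 probe sets tested on each of the 24 arrays, ordered by group, with 1 point per array.

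At 5 days the cambium on NAA was compared with the starch sheath on medium alone. NAA and the captured cell type cannot be told apart here. AT1G59740, a transporter of the NPF family, was 85.5-fold higher in the cambium (log2 change 6.42 ± 0.76 SE, adjusted p = 5.51e-05), at a mean log2 level of 9.29 ± 1.21 (SD, n = 3) against 2.87 ± 0.35, a level under the median of all values. The beta-glucosidase gene BGLU33 rose 44.9-fold (5.49 ± 0.88, adjusted p = 0.000923) and the endoglucanase family gene GH9B13 rose 34.3-fold (5.10 ± 1.06, adjusted p = 0.00885). AT3G53190, a pectin lyase-like gene, and the pectin methylesterase family gene AT3G05620 rose 37.5-fold and 17-fold. BCAT4, which acts in the methionine chain elongation that leads to glucosinolates, fell by 4.95 on the log2 scale (± 1.02 SE, adjusted p = 0.00865). AT5G05600, a 2-oxoglutarate dioxygenase gene of jasmonate oxidation, fell by 4.72 (adjusted p = 0.000174), and AT2G45180, PIFI, AT1G80130 and AT4G22470 fell (log2 changes of -4.52, -3.70, -3.65 and -3.59). In all, 458 probe sets were higher and 336 lower at an adjusted p under 0.05.

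Auxin-responsive genes were among those that rose at 5 days. GH3.3, which conjugates auxin to amino acids, was 23.9-fold higher (4.58 ± 0.83 SE, adjusted p = 0.00286), and the auxin-induced homeodomain gene HAT2 was 8.62-fold higher (3.11 ± 0.66, adjusted p = 0.00989). Of the 8 measured members of the early auxin response list these 2 rose, 0 fell and 6 did not pass, and 2 rose when adjusted over the list alone. The list ranked higher in the cambium by camera (adjusted p = 0.0357, and adjusted p = 0.619 with an estimated correlation). That call ended with array weights (0.158), without the 3 narrow arrays (0.0818), and without cambium replicate 1 or 3 or medium replicate 2 (0.0853 to 0.179). Of the 7 measured Aux/IAA repressor genes 0 rose, 0 fell and 7 did not pass, none rose when adjusted over the list alone, and the camera adjusted p was 0.225. Of the 2 measured cambium regulators, the class III HD-ZIP gene PHV was 3.09-fold higher (1.63 ± 0.43, adjusted p = 0.041), and the vascular bHLH gene LHW differed by 0.02 (adjusted p = 0.998). 1 of the pair rose when adjusted over the list alone. With the GAPDH covariate 0 of the pair (PHV at 0.235) and 1 of the 8 early auxin response genes rose. GH3.3 lay at 2.53 and 2.38 after 2 and 5 days on medium against 4.89 in untreated starch sheath, without passing (adjusted p = 0.114 and 0.0763), and in the cambium it differed from untreated by 2.06 (adjusted p = 0.128). MOL1, a receptor kinase gene that the study picked for follow-up from these arrays, differed by 1.70 ± 0.52 without passing (adjusted p = 0.0906).

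Of 9 measured nuclear photosynthesis genes on the fixed list, 4 fell in the cambium against medium, 1 rose and 4 did not pass, and 1 rose and 8 fell over the list alone. The camera adjusted p was 5.57e-08, or 0.27 with an estimated correlation, at a median log2 change of -1.57. Under the GAPDH covariate 1 rose and 8 fell, and XTH18, named below, did not pass. ATPC1, a subunit of the plastid ATP synthase, was 4.6-fold lower (-2.20 ± 0.28 SE, adjusted p = 9.45e-05), and the Rubisco activase gene RCA was 4.14-fold lower (-2.05 ± 0.39, adjusted p = 0.00407). The Calvin cycle gene SBPASE fell by 1.40 (adjusted p = 0.0139) and the photosystem I gene PSAE-1 fell by 1.66 (adjusted p = 0.0374), while the light-harvesting gene LHCB4.3 rose by 1.57 (adjusted p = 0.0059). In the longer added list of 18 photosynthesis genes 1 rose, 9 fell and 8 did not pass (adjusted p = 4.15e-14, and adjusted p = 0.219 with an estimated correlation; 13 fell with the covariate). SBE2.2, a starch branching enzyme gene, fell by 2.08 (adjusted p = 0.0121) as 1 of 2 measured genes of starch metabolism, and both fell when adjusted over the list alone. Of 7 wall loosening genes 0 rose, 1 (XTH18) fell by 1.10 and 6 did not pass, with 1 fallen when adjusted over the list alone and a camera adjusted p of 0.493.

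Among 31 measured genes of mitosis and cytokinesis in the added list, 1 rose in the cambium against medium at 5 days (AT3G51280, by 0.83, adjusted p = 0.0222), 0 fell and 30 did not pass, and 2 rose when adjusted over the list alone. The list ranked higher in the cambium (adjusted p = 2.17e-06, and adjusted p = 0.368 with an estimated correlation, median 0.22). With the GAPDH covariate 0 rose. Of 8 core histone genes 0 passed over all probe sets and 4 rose when adjusted over the list alone (camera adjusted p = 0.013, and adjusted p = 0.531 with an estimated correlation). The histone call ended without medium replicate 1 or 3 (0.0528 to 0.0534). Of 5 phloem genes in the added list 0 passed and 3 rose when adjusted over the list alone, with a camera adjusted p of 0.00346 (adjusted p = 0.0872 with an estimated correlation). CLE44, which encodes a phloem-derived peptide signal, differed by 2.26 (adjusted p = 0.0602), and the phloem call ended without dim probe sets (0.065).

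The 5-day comparison against medium rested in part on single arrays. Of 28 named calls, 21 held in every fit that left out 1 array, and 21 held when only these 6 arrays were fitted. Without cambium replicate 2, 6 were lost (adjusted p 0.0644 to 0.255), among them GH9B13, BCAT4, PHV and HAT2, and the count fell to 406. Without cambium replicate 1, 1 was lost (0.0614), and without replicate 3, 2 (0.0693 to 0.0838). Without medium replicates 1, 2 and 3 the losses were 3 (0.0536 to 0.11), 5 (0.0605 to 0.135) and 4 (0.0538 to 0.147), with counts of 463, 489 and 526. The share called higher was 57.7%, against 38.3% with the GAPDH 3' excess as a covariate and 49.1% when only the 6 arrays were fitted.

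**Figure D2:**
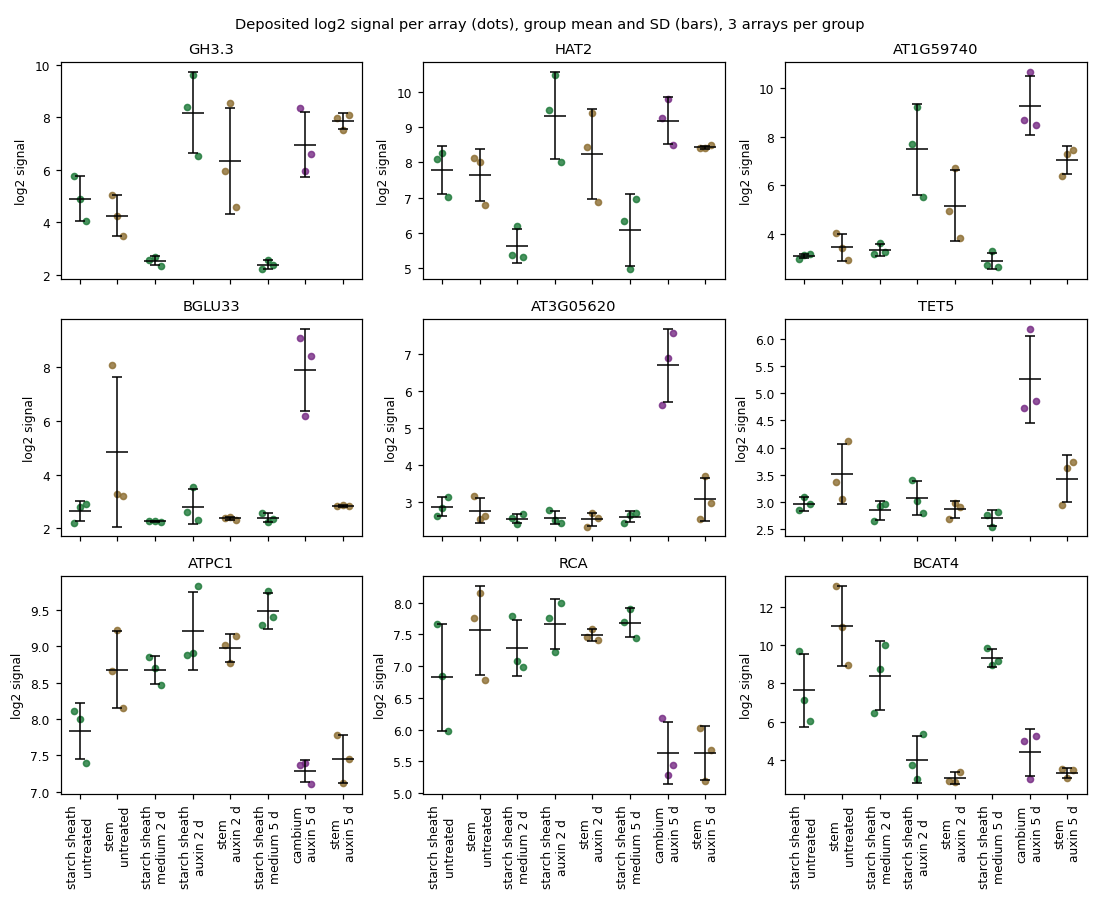
Log2 levels of 9 genes in the 8 groups, with 1 dot per array, the mean of 3 arrays and SD bars; SS is the starch sheath, MS medium alone and T0 untreated. BGLU33 and AT3G05620 are highest in the cambium at 5 days (7.88 and 6.70), GH3.3 lies at 8.17, 6.34, 6.95 and 7.85 in the 4 groups on NAA (starch sheath and stem at 2 days, cambium and stem at 5 days) against 2.53 and 2.38 on medium alone, and ATPC1 falls from 9.21 to 7.29 between 2 and 5 days on NAA.

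At 2 days, when the labels place the tissue before cell division, the starch sheath on NAA was compared with the starch sheath on medium alone. GH3.3 was 49.9-fold higher (5.64 ± 0.83 SE, adjusted p = 0.00537), HAT2 13.1-fold higher (3.71 ± 0.66, adjusted p = 0.0181) and the Aux/IAA repressor gene IAA29 6.51-fold higher (2.70 ± 0.56, adjusted p = 0.0375). AT1G14130, a dioxygenase gene of auxin oxidation, rose 2.53-fold (1.34 ± 0.17, adjusted p = 0.00198). AT1G59740 was 17.7-fold higher (4.15 ± 0.76, adjusted p = 0.019), and AT1G62480, the peroxidase gene AT5G58390 and the osmotin-like gene OSM34 rose 15.9-, 15.2- and 10.4-fold. AT5G05600, the peroxidase gene AT4G36430 and NANA were 8.53-, 8.29- and 6.26-fold lower, and AT2G41800, AT5G55290 and AT3G57790 fell (log2 changes of -1.79, -1.50 and -1.39). The comparison called 52 probe sets higher and 35 lower.

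Of the 8 early auxin response genes 3 rose at 2 days, 0 fell and 5 did not pass, and 4 rose when adjusted over the list alone (camera adjusted p = 0.000102, and adjusted p = 0.218 with an estimated correlation). Of 7 Aux/IAA repressor genes 1 rose, 0 fell and 6 did not pass, 2 rose when adjusted over the list alone, and the camera adjusted p was 0.161. Of the 9 photosynthesis genes 0 rose, 0 fell and 9 did not pass, and none did when adjusted over the list alone. They ranked higher with auxin (adjusted p = 0.0032, and adjusted p = 0.619 with an estimated correlation), a call that ended with cyclic loess (0.282) or quantile normalization (0.285). PRK and LHCB4.1 of this list differed by 1.79 (adjusted p = 0.311) and 1.32 (adjusted p = 0.32). Of 121 cytosolic ribosomal protein genes in the added lists 2 rose, 0 fell and 119 did not pass, and 5 rose when adjusted over the list alone (camera adjusted p = 2.6e-14, and adjusted p = 0.515 with an estimated correlation). In the fit with the GAPDH covariate 40 of the 121 and 2 of the 9 photosynthesis genes rose. MOL1 differed by 0.43 (adjusted p = 0.824). The 7 wall loosening genes were not called (0.965).

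The 2-day count rested on few arrays. It was 10 without NAA replicate 2, 57 and 17 without medium replicates 1 and 2 (33.3% higher in the former fit and 41.0% without medium replicate 3, against 59.8%), and 2 when only the 6 arrays were fitted. The 3' excess of the GAPDH control was 6.14 to 6.67 on NAA and 6.71 to 7.43 on medium, and with this excess as a covariate 1782 probe sets were called. Of 14 named calls AT1G14130 and OSM34 held in every fit that left out 1 array. Without medium replicates 1, 2 and 3, 7 (adjusted p 0.056 to 0.171), 11 (0.0561 to 0.152) and 8 (0.0524 to 0.0779) were lost. Without NAA replicates 1, 2 and 3, 7 (0.0505 to 0.0839), 12 (0.0521 to 0.258, GH3.3 at 0.0521) and 2 (0.0868 to 0.132) were lost.

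To separate the cambium from a response of the whole stem, it was compared at 5 days with the surrounding stem of the same treatment. BGLU33 was 33.2-fold higher in the cambium (5.05 ± 0.88 SE, adjusted p = 0.0115), and AT3G05620 12.3-fold higher (3.62 ± 0.34, adjusted p = 6.45e-05). The thaumatin-like genes ATLP-1 and AT2G28790, the leucine-rich repeat kinase gene AT1G67720, the glycosyl hydrolase gene AT5G42720 and AT1G14730 were higher by 3.6, 2.39, 2.69, 2.54 and 2.49. The flavin monooxygenase gene FMO and the tetraspanin gene TET5 were 4.67- and 3.54-fold higher (adjusted p = 0.0211 and 0.0114). AT1G09310 was 34.6-fold lower (-5.11 ± 1.05, adjusted p = 0.041) and the chitinase gene CHI 3.46-fold lower (-1.79 ± 0.30, adjusted p = 0.0112). AT5G24210, AT3G22240, AT5G20400 and AT5G38900 were lower (log2 changes of -2.48, -2.3, -1.72 and -1.40). The comparison called 57 probe sets higher and 24 lower. MOL1 and LHW differed by 1.39 (adjusted p = 0.601) and 0.90 (adjusted p = 0.368).

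Of the 31 mitosis and cytokinesis genes 0 passed in this comparison, and none when adjusted over the list alone. Their list ranked higher in the cambium (camera adjusted p = 7.74e-05, median 0.15, and adjusted p = 0.515 with an estimated correlation), which ended with array weights (0.303) and without cambium replicate 2 or stem replicate 1 (0.0513 to 0.677). The 33 plastid-encoded photosynthesis genes ranked higher as well, with 0 passed and 2 risen when adjusted over the list alone (adjusted p = 0.0172, and adjusted p = 0.774 with an estimated correlation). That call ended without cambium replicate 1 or 3 or stem replicate 2 or 3 (0.0536 to 0.47).

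53 probe sets, 33 of them with 1 named gene, were higher in the cambium than in all 3 of the untreated starch sheath, the starch sheath on medium at 5 days and the surrounding stem on NAA at 5 days, and 0 were lower in all 3 by limma. The corresponding counts at an unadjusted p under 0.05 were 436 and 31. BGLU33 was 37.9-fold above the untreated starch sheath (5.25 ± 0.88 SE), AT3G05620 14.1-fold (3.82 ± 0.34), ATLP-1 21.1-fold (4.40 ± 0.76) and FMO 27.4-fold (4.78 ± 0.42). AT1G67720, AT5G42720, AT1G14730, AT2G28790, TET5 and AT1G80690 stood 12.8-, 9.41-, 7.55-, 6.5-, 4.9- and 4.07-fold above it. Independent lists of these sizes would share 0.0689 higher probe sets, and 20 simulations of unchanged groups shared 47.1 higher and 48.1 lower on average at an unadjusted p under 0.05. Part of the excess may come from the cambium arrays that all 3 comparisons share.

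The 5-day cambium set depended on the arrays compared. The count was 87, 16 and 82 without cambium replicates 1, 2 and 3 and 13, 32 and 18 without stem replicates 1, 2 and 3. It was 2 when only the compared groups were fitted. Of the 16 named calls between cambium and stem, AT3G05620 and AT1G14730 held in every fit that left out 1 array. Without cambium replicates 1, 2 and 3, 2 (adjusted p 0.0526 to 0.1), 13 (0.0635 to 0.354) and 3 (0.0993 to 0.122) were lost, and the comparison's count was 125 without replicate 1 and 25 without replicate 2. Without stem replicates 1, 2 and 3, 12 (0.0518 to 0.262), 7 (0.0691 to 0.109) and 11 (0.0597 to 0.167) were lost, with counts of 34, 52 and 30. The share called higher was 70.4%, against 38.2% without stem replicate 1 and 40% when only the 6 arrays were fitted. BGLU33 was among those lost without stem replicates 1 and 3.

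At 2 days on NAA the starch sheath was compared with the surrounding stem, before divisions began. AT5G58390 was 13.6-fold higher in the starch sheath (3.76 ± 0.74 SE, adjusted p = 0.0385, or 0.0558 with the replicate as a block). The receptor kinase-like gene AT4G37250 was 3.47-fold higher (1.79, adjusted p = 0.0154), and AT3G04000 was higher by 1.74. AT1G14130 was 1.88-fold higher (0.91 ± 0.17, adjusted p = 0.0248, or 0.0544 with the block). AT1G19450 and AT4G21620 were 5.14- and 6.07-fold lower (-2.36 ± 0.36 and -2.60 ± 0.41, adjusted p = 0.00756 and 0.00792). AT4G16240 and AT3G16370 were lower (log2 changes of -2.44 and -2.33), and AT1G29670 and AT4G22470 were lower (log2 changes of -2.89 and -2.74). GH3.3 and HAT2 differed by 1.83 and 1.09 without passing (adjusted p = 1 for both, or 0.13 and 0.0746 with the block over these 6 arrays). The comparison called 11 probe sets higher and 45 lower, 41 in all with the block.

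Replicate numbers paired these 2 groups at 2 days. Beside AT5G58390 and AT1G14130, the block ended the calls of AT5G49440 (0.0385 to 0.066), AT2G25870 (0.049 to 0.0843), AT1G29670 (0.0491 to 0.0732) and AT4G22470 (0.0494 to 0.0903). When only these 6 arrays were fitted with the block, 26 probe sets were called, 10 higher and 16 lower, of which 13 were among the 56. In that fit AT4G37250, AT4G21620, AT1G19450 and AT1G29670 passed (adjusted p 0.0299, 0.0225, 0.025 and 0.0176) and the other 8 of the 12 named genes did not. Without NAA replicates 2 and 3 the count was 18 and 37, and without stem replicates 1 and 2 it was 28 and 37. Of the 12 named calls, 7 (0.0877 to 0.219), 10 (0.0755 to 0.343) and 5 (0.0672 to 0.153) were lost without starch sheath replicates 1, 2 and 3. Without stem replicates 1, 2 and 3, 9 (0.0844 to 0.322), 7 (0.052 to 0.184) and 7 (0.0525 to 0.2) were lost, and AT1G19450 and AT4G21620 held throughout.

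Of the 8 early auxin response genes 1 (AT1G14130) was higher in the starch sheath than in the stem at 2 days, 0 were lower and 7 did not pass, with 1 higher when adjusted over the list alone. The list ranked higher in the starch sheath (camera adjusted p = 0.00691, and adjusted p = 0.498 with an estimated correlation), but not without NAA replicate 2 or stem replicate 1 or 3 (0.0542 to 0.189). Of 31 mitosis and cytokinesis genes 0 passed and none did when adjusted over the list alone, while their list ranked higher (adjusted p = 1.54e-06, and adjusted p = 0.36 with an estimated correlation), except without NAA replicate 2 (0.0531). The 5 added phloem genes, of which 0 passed, ranked higher (adjusted p = 0.0435, and adjusted p = 0.23 with an estimated correlation), which ended with the block (0.0525), without dim probe sets (0.106), and without starch sheath replicate 1 or 2 or stem replicate 1 or 3 (0.0929 to 0.151).

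3 probe sets were higher after 2 days on NAA than in all 3 of the untreated starch sheath, the starch sheath on medium and the surrounding stem on NAA. The only 1 with a named gene was AT1G14130, by 0.91, 1.34 and 0.91 on the log2 scale. With the replicate as a block its difference between the tissues no longer passed (0.0544) and 2 probe sets were left. Its level was 4.36 ± 0.31 (SD, n = 3) in the starch sheath on NAA, 3.45 ± 0.22 untreated, 3.02 ± 0.20 on medium and 3.45 ± 0.11 in the stem on NAA. The other two, 244979_at and 252282_at, rose by 0.94 and 2.70 over untreated tissue, and are named after their values were seen. By limma 0 probe sets were lower in all 3, and 154 were higher and 19 lower at an unadjusted p under 0.05. Independent lists would share 0.00188 higher probe sets, 20 simulations of unchanged groups shared 49.1 higher and 47.1 lower on average at the unadjusted threshold, and part of the excess may come from the shared arrays. The count was 5 without untreated starch sheath replicate 1 or NAA replicate 3, 1 without medium replicate 1, 2 or 3, and 0 without NAA replicate 2 or stem replicate 1 or 3.

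Between 2 and 5 days on NAA, as the starch sheath gave way to cambium, AT5G10040 and AT4G10270 rose 37.3- and 24-fold (5.22 ± 0.25 and 4.59 ± 0.38 SE, adjusted p = 3.87e-10 and 1.54e-06). BGLU33 rose 33.7-fold (5.07 ± 0.88, adjusted p = 0.00315), AT3G05620 17.3-fold (4.11 ± 0.34, adjusted p = 1.54e-06), and AT1G33055 and AT5G17980 14.5- and 12.9-fold. AT1G09310 and the beta-glucosidase gene BGLU44 fell (log2 changes of -4.23 and -3.73), and ALDH11A3, psbI and PIFI fell (log2 changes of -2.95, -2.75 and -2.62). AT1G14130 fell by 0.72 (adjusted p = 0.035). MOL1 differed by 1.19 without passing (adjusted p = 0.361). In this comparison 270 probe sets were higher and 190 lower.

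Of the 9 fixed photosynthesis genes 4 fell between 2 and 5 days, 0 rose and 5 did not pass, and 6 fell when adjusted over the list alone (camera adjusted p = 2.98e-11, and adjusted p = 0.218 with an estimated correlation). ATPC1 was 3.79-fold lower (-1.92 ± 0.28 SE, adjusted p = 0.000604), SBPASE 3.38-fold lower (adjusted p = 0.00387), RCA 4.07-fold lower (adjusted p = 0.00721), and PRK, another Calvin cycle gene, 7.62-fold lower (adjusted p = 0.0229). In the added list of 18, 0 rose, 6 fell and 12 did not pass (adjusted p = 9.24e-18, and adjusted p = 0.131 with an estimated correlation). The 33 plastid-encoded genes ranked lower, with psbI the 1 that fell (adjusted p = 1.2e-05, and adjusted p = 0.515 with an estimated correlation). Of 121 ribosomal protein genes 0 rose, 4 fell and 117 did not pass (adjusted p = 6.39e-26, and adjusted p = 0.279 with an estimated correlation). Under the GAPDH covariate 22 of these, 5 of the 9, 10 of the 18 and 3 of the 33 genes fell. The 20 ribosome biogenesis genes ranked lower with 1 fallen (adjusted p = 5.41e-06, and adjusted p = 0.131 with an estimated correlation), and the 5 phloem genes ranked higher with 0 passed (adjusted p = 0.0142, and adjusted p = 0.131 with an estimated correlation; 0.0501 without dim probe sets).

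The count between 2 and 5 days was 286 and 197 without 2-day replicates 1 and 3, and 250 without cambium replicate 2. The share called higher was 58.7%, against 44.9% without the 3 narrow arrays, 42.9% with the GAPDH covariate and 49.5% with array weights. Of 16 named calls, 8 held in every fit that left out 1 array: AT5G10040, AT4G10270, AT3G05620, AT1G33055, AT5G17980, BGLU33, ATPC1 and SBPASE. Without cambium replicates 1, 2 and 3, 1 (adjusted p 0.0508), 6 (0.0509 to 0.186) and 7 (0.0571 to 0.181) were lost. Without 2-day replicates 1, 2 and 3, 4 (0.0667 to 0.142), 3 (0.0699 to 0.143) and 7 (0.0539 to 0.178) were lost.

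Cultured tissue was compared with the untreated starch sheath, from which it also differed in the GAPDH 3' excess. After 2 days on NAA 104 of 121 ribosomal protein genes rose, 0 fell and 17 did not pass, and 107 rose when adjusted over the list alone (median log2 change 2.56, camera adjusted p = 2.9e-73, and adjusted p = 0.0724 with an estimated correlation). After 2 days on medium alone 72 rose and 0 fell, after 5 days on medium 58 rose and 0 fell, and in the cambium 75 rose and 0 fell. Their camera adjusted p was 1.66e-67, 9.34e-45 and 3.09e-45, or 0.0724, 0.126 and 0.126 as adjusted p with an estimated correlation. AT2G44120 was 19.3-fold higher after 2 days on NAA (4.27 ± 0.58 SE, adjusted p = 0.000159) and 17.1-fold higher on medium (4.1 ± 0.58, adjusted p = 0.000359), and AT3G07110 and AT3G09200 rose 19.4- and 19.2-fold on NAA. Of 20 ribosome biogenesis genes 8 rose after 2 days on NAA and 0 fell (adjusted p = 5.01e-09, and adjusted p = 0.0724 with an estimated correlation). Ribosomal genes kept their direction under cyclic loess and quantile normalization, and against untreated replicate 1 alone. With the GAPDH covariate 2 of the 121 rose after 2 days on NAA, 1 and 6 after 2 and 5 days on medium and 0 in the cambium, at medians of 0.98, 0.12, 0.38 and 0.18. Of the ribosome biogenesis genes 0 passed in that fit after 2 days on NAA.

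Other genes separated the starch sheath after 2 days on NAA from untreated tissue. ARL, a relative of the organ size gene ARGOS, was 28.4-fold higher (4.83 ± 0.44 SE, adjusted p = 7.85e-06), the formate dehydrogenase gene FDH 24.2-fold higher (4.6 ± 0.72, adjusted p = 0.000536) and AT1G59740 21.3-fold higher (4.41 ± 0.76, adjusted p = 0.00114). GH3.3, IAA29 and AT1G14130 rose 9.73-, 4.11- and 1.88-fold (adjusted p = 0.0164, 0.025 and 0.00231). Both measured cambium regulators rose, PHV by 1.65 (adjusted p = 0.0189) and LHW by 1.16 (adjusted p = 0.0155), and both rose when adjusted over the list alone. In the fit with the GAPDH covariate PHV and LHW differed by 0.18 and 0.41 (adjusted p = 0.95 and 0.811), and 0 of the 8 early auxin response genes passed. JKD, a zinc finger gene and the only measured member of the starch sheath identity list, fell by 0.93 (adjusted p = 0.0334) and did not pass with the covariate. BCAT4, AT1G75280, AT1G22480, AT5G06930, AT2G16660 and TBL38 fell (log2 changes of -3.63, -3.33, -3.28, -3.22, -2.996 and -2.83).

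In the cambium at 5 days AT1G59740 stood 74.4-fold above the untreated starch sheath (6.22 ± 0.76 SE, adjusted p = 5.79e-05) and ARL 40.2-fold (5.33 ± 0.44, adjusted p = 8.66e-07). AT1G19530, AT5G10040 and AT4G10270 stood 33.2-, 30.8- and 30.1-fold above it. PHV was 6.58-fold higher (2.72 ± 0.43, adjusted p = 0.000585) and LHW 3.15-fold higher (1.65 ± 0.29, adjusted p = 0.00137), so that both cambium regulators rose, also when adjusted over the list alone. MOL1 rose 3.31-fold (1.73 ± 0.52, adjusted p = 0.0474), a gene the study picked on these arrays and so no independent evidence. With the GAPDH covariate its change turned to -0.18 (adjusted p = 0.939), PHV and LHW differed by 1.06 and 0.80 (adjusted p = 0.478 and 0.462), JKD did not pass, and 0 of the plastid-encoded genes fell. Over all settings the adjusted p of MOL1 ran from 0.00137 to 0.939. JKD fell by 0.89 (adjusted p = 0.0467), and AT1G22480, AT1G80170, AT5G06930, AT1G07280, AT2G16660 and ALDH11A3 fell (log2 changes of -4.59, -3.97, -3.55, -3.29, -2.99 and -2.98). Of 33 plastid-encoded photosynthesis genes 0 rose, 5 fell and 28 did not pass (camera adjusted p = 0.000203, and adjusted p = 0.57 with an estimated correlation), a call that ended without untreated starch sheath replicate 1 (0.159).

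On medium alone the starch sheath also moved away from the untreated state. AT4G12490 was 49.1-fold higher at 2 days (5.62 ± 0.98 SE, adjusted p = 0.00195) and 14.8-fold at 5 days (3.89 ± 0.98, adjusted p = 0.0236), and the plastid chaperonin gene Cpn60beta2 was 20.9-fold higher at 2 days (4.39 ± 0.45, adjusted p = 2.37e-05). AT3G15720 rose 19.2- and 12.7-fold at the respective times. At 2 days AT1G70780 and AT1G77940 rose 18.3- and 16.6-fold, and AT5G06930, AT2G32150, TBL38, AT3G23090, PME61 and AT1G47410 fell (log2 changes of -2.88, -2.66, -2.66, -2.65, -2.55 and -2.54). At 5 days AT5G52450, FDH, AT2G25450 and AT1G74470 rose 18.1-, 17.1-, 13.3- and 13.2-fold, and AT1G22480, AT1G80170, AT1G75280, AT1G47410, AT2G23360 and AT5G06930 fell (log2 changes of -5.34, -4.89, -4.35, -3.29, -3.28 and -3.23). LHW rose 3.1-fold at 5 days on medium (1.63 ± 0.29, adjusted p = 0.00243), 1 of 2 cambium regulators, while both rose when adjusted over the list alone, and JKD fell by 1.15 (adjusted p = 0.0165). Both measured starch metabolism genes rose at 5 days, SBE2.2 by 2.12 (adjusted p = 0.00924) and DPE1 by 1.62 (adjusted p = 0.0354). LHW (adjusted p = 0.177), JKD and both starch genes did not pass with the GAPDH covariate.

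Of 11 measured genes of xylan and secondary wall formation, compared with untreated tissue, 5 fell in the starch sheath after 2 days on NAA and 6 in the cambium, 1 and 4 after 2 and 5 days on medium, and 2 and 1 in the stem after 2 and 5 days on NAA, and 0 rose. In the cambium the xylan genes IRX15, IRX15-L and GUT2 fell (log2 changes of -2.1, -1.81 and -1.62, adjusted p = 0.000854, 0.0177 and 0.0166). The list's camera adjusted p in that order was 0.00326, 0.000354, 0.000103, 7.27e-06, 1.75e-06 and 7.73e-07, or as adjusted p with an estimated correlation 0.368, 0.273, 0.219, 0.131, 0.126 and 0.126. Without untreated starch sheath replicate 1 the calls on NAA at 2 days (0.142), in the cambium (0.0708) and on medium at 2 days (0.0719) ended. The direction was the same under every scaling run. With the GAPDH covariate 0, 0, 0, 2, 1 and 2 of the genes fell in the same order, at medians of -1.75, -1.65, -1.81, -1.88, -1.63 and -1.31.

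Photosynthesis genes had no fixed direction against the untreated starch sheath. Of the 9 fixed genes ATPC1 (1.38, adjusted p = 0.00361) and PRK (2.52, adjusted p = 0.0187) rose after 2 days on NAA and 7 did not pass, with 2 risen when adjusted over the list alone, and the list ranked higher (adjusted p = 0.00495, and adjusted p = 0.619 with an estimated correlation). Under cyclic loess the list ranked lower (0.0311), as it did with quantile normalization (0.16) and without the 3 narrow arrays (0.712), and it was not called without dim probe sets (0.0738) or without untreated starch sheath replicate 3 (0.17). ATPC1 itself turned to -0.38 with cyclic loess (adjusted p = 0.601) and -0.10 with quantile normalization (adjusted p = 0.892), and over all settings its adjusted p ran from 0.00165 to 0.892. After 5 days on medium ATPC1 rose by 1.66, LHCB4.3 fell by 1.18 and 7 did not pass, 1 rose and 1 fell when adjusted over the list alone, and the list ranked higher (adjusted p = 0.0141, and adjusted p = 0.619 with an estimated correlation). That rank turned lower with cyclic loess (0.0443), quantile normalization (0.379) and without the narrow arrays (0.281), and ended without dim probe sets (0.11) or without untreated replicate 3 or medium replicate 2 (0.125 to 0.44). Under the GAPDH covariate 0 of the 9 genes passed in either comparison, at medians of 0.09 and -0.08.

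The share of probe sets called higher depended on the scaling and on the GAPDH covariate in these comparisons. After 2 days on NAA 1699 were higher and 973 lower, or 63.6% higher, against 55.3% with cyclic loess, 56.9% with quantile normalization and 35.6% without the 3 narrow arrays. The cambium had 1365 higher and 587 lower, 69.9% against 52.7%, 57.1% and 32.1% in the same order. Medium alone gave 904 higher and 220 lower at 2 days, 80.4% against 56.7%, 64.9% and 27.9%, and 983 higher and 460 lower at 5 days, 68.1% against 49.5%, 59.9% and 24.9%. With the GAPDH covariate 10, 111, 359 and 327 probe sets were called, 60%, 40.5%, 18.4% and 35.5% of them higher, and with array weights the shares were 42.9%, 44.2%, 51.8% and 44.6%.

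Untreated starch sheath replicate 1, the 1 array of its group with the wider spread, moved all 4 of these counts. Without it 8195 probe sets were called after 2 days on NAA, 5798 in the cambium, and 4376 and 5616 after 2 and 5 days on medium (41.4%, 44.7%, 47% and 42.3% higher). Without untreated replicate 2 the 4 counts were 1167, 1141, 622 and 641, and without replicate 3 those on NAA at 2 days and on medium at 5 days were 1300 and 866. Leaving out NAA replicates 2 and 3 gave 1232 and 1099, cambium replicates 1 and 2 gave 1218 and 819, medium replicate 3 at 2 days gave 708, and medium replicates 1 and 2 at 5 days gave 675 and 518. Of 20 named calls on NAA at 2 days, leaving out NAA replicates 1, 2 and 3 ended 4 (adjusted p 0.0548 to 0.0802), 6 (0.0564 to 0.142) and 5 (0.0951 to 0.144), and leaving out untreated replicates 1, 2 and 3 ended 2 (0.0587 to 0.0737), 9 (0.0506 to 0.136) and 5 (0.0641 to 0.171). Of 25 in the cambium, AT2G16660, JKD and MOL1 were lost without cambium replicate 1 (0.0558 to 0.116), and JKD and MOL1 without cambium replicate 2 (0.223 to 0.295) and untreated replicates 2 (0.103 to 0.177) and 3 (0.128 to 0.213). Of 12 on medium at 2 days, AT2G32150, AT3G23090 and PME61 were lost without medium replicates 1 (0.088 to 0.116), 2 (0.0614 to 0.116) and 3 (0.0589 to 0.0919), and the latter pair without untreated replicates 1 (0.0624 to 0.0758) and 2 (0.0659 to 0.083). Of 16 on medium at 5 days, 4 (0.0796 to 0.118), 5 (0.0577 to 0.135) and 1 (0.0828) were lost without medium replicates 1, 2 and 3, and 4 (0.0705 to 0.155) and 3 (0.0638 to 0.13) without untreated replicates 2 and 3.

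**Figure D3:**
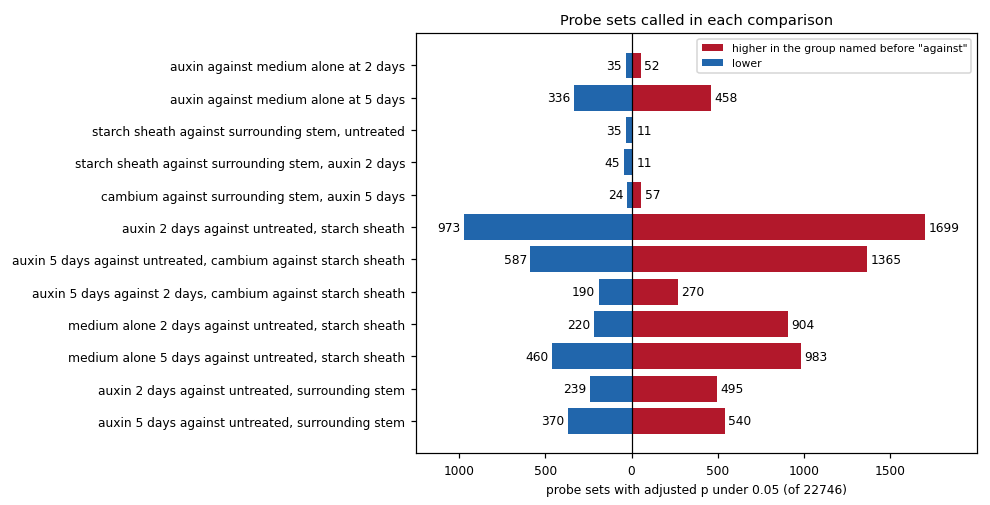
Number of probe sets called higher (bars to the right) and lower (bars to the left) at an adjusted p under 0.05 in 12 comparisons of 3 arrays against 3. The comparisons with the untreated starch sheath reach 1699 higher and 973 lower, those between tissues at most 57 higher and 45 lower.

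No group of surrounding stem on medium alone is among the samples, so NAA and culture cannot be told apart in its changes from untreated tissue. After 2 days on NAA GH3.3 differed by 2.09 in the stem without passing (adjusted p = 0.215), and ARL rose 16.3-fold (4.03 ± 0.44 SE, adjusted p = 9.63e-05), AT4G22470 15.8-fold (3.98 ± 0.57, adjusted p = 0.000728) and FDH 15.3-fold (3.94 ± 0.72, adjusted p = 0.00487). AT5G52450, AT5G22460 and AT3G15720 rose 10.9-, 9.66- and 9.57-fold. Of these FDH, AT5G52450 and AT3G15720 also rose in the starch sheath after 5 days on medium alone. BCAT4 fell by 7.99 (± 1.02, adjusted p = 0.000317), and AT1G75280, AT1G67865, AT1G21440, AT1G22480 and AT3G45160 fell (log2 changes of -4.51, -4.45, -4.04, -3.79 and -3.79). Of 121 ribosomal protein genes 69 rose, 0 fell and 52 did not pass (camera adjusted p = 8.98e-67, and adjusted p = 0.0724 with an estimated correlation), and of 20 ribosome biogenesis genes 5 rose and 0 fell (adjusted p = 8.88e-14, and adjusted p = 0.0514 with an estimated correlation). CLE41 fell by 1.50 (adjusted p = 0.0412), as 1 of 4 measured phloem genes and also over the list alone. In all 495 probe sets were higher and 239 lower.

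By 5 days on NAA the stem showed AT5G10040 89-fold higher than untreated, where it lay at 2.61 (6.47 ± 0.25 SE, adjusted p = 8.07e-12), OSM34 39.3-fold (5.30 ± 0.47, adjusted p = 2.21e-06) and AT4G10270 27.6-fold (4.79 ± 0.38, adjusted p = 6.41e-07). AT4G12490, ARL and AT4G39675 rose 19.1-, 18.7- and 15.2-fold. BCAT4 and AT1G29670 fell (log2 changes of -7.70 and -4.2), and ALDH11A3, AT1G22480, the endoglucanase family gene GH9B7 and AT1G21440 fell (log2 changes of -3.96, -3.89, -3.87 and -3.73). GH3.3 rose 12.1-fold (3.6 ± 0.83, adjusted p = 0.0171), the 1 of 8 early auxin response genes to do so, with 2 risen when adjusted over the list alone (camera adjusted p = 0.00877, and adjusted p = 0.498 with an estimated correlation; 0.0523 without untreated stem replicate 1). Of the 9 photosynthesis genes in the stem 0 rose, 5 fell and 4 did not pass, and 8 fell when adjusted over the list alone (camera adjusted p = 2.38e-09, and adjusted p = 0.218 with an estimated correlation). PSAN, RCA, PSAE-1 and ATPC1 fell (log2 changes of -2.72, -1.93, -1.98 and -1.23, adjusted p = 0.00452, 0.00694, 0.0117 and 0.0142). In the added list of 18, 8 fell (adjusted p = 8.51e-14, and adjusted p = 0.219 with an estimated correlation), and of 121 ribosomal protein genes 23 rose (adjusted p = 2.15e-31, and adjusted p = 0.219 with an estimated correlation). CLE44 rose by 2.52 (adjusted p = 0.032), as 1 of 4 phloem genes and also over the list alone, and 540 probe sets were higher and 370 lower.

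The share called higher in the stem was 67.4% at 2 days and 59.3% at 5 days, against 51.6% and 47.8% with cyclic loess, 57.0% and 56.8% with quantile normalization, 38.1% and 33.6% without the 3 narrow arrays, 49.2% and 48.7% with array weights, and 19.9% and 28% with the GAPDH covariate, which left 3 and 1 of the ribosomal protein genes risen. At 5 days 6 of the 9 and 11 of the 18 photosynthesis genes fell with the covariate, and 0 early auxin response and phloem genes rose. The 2-day count was 484 without untreated stem replicate 3 and 339 and 349 without NAA replicates 1 and 3. The 5-day count was 439 and 408 without NAA replicates 2 and 3. Of 12 named calls at 2 days, leaving out NAA replicates 1, 2 and 3 ended 2 (adjusted p 0.0641 to 0.0872), 2 (0.0581 to 0.0735) and 3 (0.0843 to 0.1), and leaving out untreated replicates 1 and 2 ended 2 (0.0516 to 0.0606) and 3 (0.0525 to 0.0693). Of 17 at 5 days, NAA replicates 1, 2 and 3 ended 2 (0.0527 to 0.0675), 2 (0.0721 to 0.0902) and 4 (0.0563 to 0.0909), and untreated replicates 2 and 3 ended 3 (0.0524 to 0.0832) and 1 (0.0657, GH3.3).

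Between the untreated tissues AT5G23430, AT5G38170 and AT3G08570 were 2.07-, 1.92- and 1.76-fold higher in the starch sheath (1.05 ± 0.19, 0.94 ± 0.18 and 0.81 ± 0.13 SE, adjusted p = 0.0311, 0.0398 and 0.00904). AT1G79630, AT3G11180 and AT4G05640 were 1.61-, 1.48- and 1.4-fold higher. AT2G05540 and AT1G29670 were 10- and 8.28-fold lower (-3.33 ± 0.59 and -3.05 ± 0.59, adjusted p = 0.0288 and 0.0405), and AT3G10860, AT3G26960, the RING finger gene ATL8 and AT1G75900 were lower (log2 changes of -2.40, -2.15, -1.54 and -1.46). JKD stood at 3.98 ± 0.68 (SD, n = 3) in the starch sheath against 2.97 ± 0.16, which did not pass over all probe sets and was higher over the list alone. Of 121 ribosomal protein genes 0 passed and 6 were lower over the list alone, and the list ranked lower in the starch sheath (camera adjusted p = 6.87e-17, or 0.468 with an estimated correlation). The GAPDH excess was 3.93 to 4.83 in the starch sheath and 4.59 to 5.50 in the stem, and with it as a covariate the median over the ribosomal genes went from -0.73 to -0.10. Of 9 photosynthesis genes 0 passed and 2 were lower over the list alone (adjusted p = 0.000769, or 0.619 with an estimated correlation). Their rank turned higher with cyclic loess (0.94) and without the narrow arrays (0.893), and the call also ended with quantile normalization (0.866) and without starch sheath replicate 3 (0.17). The 33 plastid-encoded genes ranked higher (adjusted p = 0.000178, and adjusted p = 0.57 with an estimated correlation), except with array weights (0.177) and without starch sheath replicate 1 or stem replicate 1 (0.0599 to 0.416).

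The untreated comparison called 11 probe sets higher and 35 lower. The share higher was 23.9%, against 19.5% with cyclic loess, 36.4% with quantile normalization and 54.7% with array weights. Without starch sheath replicates 1 and 3 it was 59.3% and 58.1%. Most calls turned higher without the 3 narrow arrays, a fit with 1 starch sheath array. The count was 3938 and 19 without starch sheath replicates 1 and 2, and 29, 24 and 215 without stem replicates 1, 2 and 3. Of 12 named calls, 10 (adjusted p 0.0673 to 0.205) and 8 (0.0609 to 0.157) were lost without starch sheath replicates 2 and 3, and 9 (0.0633 to 0.168), 9 (0.0543 to 0.165) and 1 (0.0612) without stem replicates 1, 2 and 3. When only the 6 arrays were fitted, limma called 0.

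The added lists of autophagy, dehydration, expansin and DNA replication genes were called in 5, 1, 1 and 3 of 14 comparisons. The 10 autophagy genes ranked lower in the untreated starch sheath than in the stem (camera adjusted p = 2.1e-05, and adjusted p = 0.435 with an estimated correlation), with 0 passed and 2 lower when adjusted over the list alone, though not without the 3 narrow arrays (0.299). The 12 dehydration genes ranked lower there too with 0 passed (adjusted p = 0.0395, and adjusted p = 0.515 with an estimated correlation), which ended under cyclic loess (0.145), quantile normalization (0.0941), without the narrow arrays (0.47), without dim probe sets (0.118), and without starch sheath replicate 2 or 3 or stem replicate 1 or 2 (0.115 to 0.289). Of 27 expansin and XTH genes 0 rose, 2 fell and 25 did not pass after 2 days on NAA against untreated starch sheath (adjusted p = 0.0172, and adjusted p = 0.656 with an estimated correlation), which ended without the narrow arrays (0.639) and without untreated replicate 2 (0.0531), with 0 passed under the GAPDH covariate. The 6 DNA replication genes ranked higher in the stem after 2 days on NAA (adjusted p = 0.0154, or 0.295 with an estimated correlation). Without untreated or NAA replicate 1 this ended (0.0626 to 0.0923). Of them 1 rose, or 0 under the covariate, at medians of 0.17 and 0.16. Heat shock proteins (8 genes), tau-class glutathione transferases (11) and UDP-glycosyltransferases (47) were called in 0 of 14 comparisons by camera, with lowest adjusted p-values of 0.119, 0.193 and 0.179 and 1, 0 and 0 comparisons at an unadjusted p under 0.05. Among the fixed lists with fewer than 5 measured genes, no member of those for mitosis, DNA replication, D cyclins, auxin transport, cytokinin, jasmonate, senescence, epidermis, monolignols and the nucleolus passed over all probe sets in any of the 14 comparisons by limma.

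Whether the change from untreated tissue to culture on NAA differed between tissues was tested as an interaction of tissue and time, which does not separate NAA from culture. From untreated to 5 days BGLU33 rose by 7.26 ± 1.24 SE more on the log2 scale in the interfascicular region than in the stem (adjusted p = 0.0437), or by 5.66 without untreated stem replicate 1 (adjusted p = 0.00215), and AT3G05620 by 3.52 ± 0.49 more (adjusted p = 0.00982). AT3G05620 lay at 2.88 and 6.70 untreated and at 5 days in the interfascicular region, and at 2.78 and 3.09 in the stem, while BGLU33 lay at 2.64 and 7.88 against 4.85 ± 2.78 (SD, n = 3) and 2.83 ± 0.02. In all 7 probe sets had a more positive change in the interfascicular region at 5 days and 0 a more negative change by limma (23 and 3 with cyclic loess, 27 and 7 with quantile normalization, 24 and 74 without the 3 narrow arrays, 464 and 637 without untreated starch sheath replicate 1, and 2037 and 2354 with array weights), with 2066 at an unadjusted p under 0.05. At 2 days both probe sets that passed are unnamed and had a more negative change, 0 had a more positive change by limma (13 more positive and 3 more negative without untreated stem replicate 3, 241 and 354 without untreated starch sheath replicate 1, 796 and 832 with array weights, and 9 and 61 without the 3 narrow arrays), and 1401 passed at an unadjusted p under 0.05. At 5 days PHV and LHW both had a more positive change when adjusted over their list of 2 measured genes alone, and neither passed over all probe sets.

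The 121 ribosomal protein genes ranked higher in the interaction at 2 days (camera adjusted p = 3.78e-23, and adjusted p = 0.335 with an estimated correlation) and at 5 days (6.95e-11, and adjusted p = 0.57 with an estimated correlation), with 0 passed at either time, and the call at 5 days ended with cyclic loess (0.0743). The 9 photosynthesis genes ranked higher in the interaction at 2 days (camera adjusted p = 0.000102, and adjusted p = 0.556 with an estimated correlation) and at 5 days (0.00395, and adjusted p = 0.619 with an estimated correlation), with 0 of the genes passed at either time. These calls ended with cyclic loess (0.23 and 0.776), quantile normalization (0.18 and 0.77) and without the narrow arrays (0.687 and 0.912), and at 5 days without untreated starch sheath replicate 3 or cambium replicate 1 (0.053 to 0.17). The interaction count at 2 days was 595 and 4 without untreated starch sheath replicates 1 and 3, 4 and 16 without untreated stem replicates 1 and 3, 0 without starch sheath replicate 2 on NAA, and 0, 0 and 4 without stem replicates 1, 2 and 3 on NAA. At 5 days it was 1101 and 4 without untreated starch sheath replicates 1 and 2, 13, 17 and 49 without untreated stem replicates 1, 2 and 3, 54, 4 and 19 without cambium replicates 1, 2 and 3, and 2 and 1 without stem replicates 2 and 3 on NAA. BGLU33 was lost without cambium replicate 3 (0.0525), untreated starch sheath replicate 2 (0.0903) or 3 (0.0596), or stem replicate 1 (0.0827), 2 (0.0861) or 3 (0.0897) at 5 days. AT3G05620 was lost without stem replicate 3 at 5 days (0.0511).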

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

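The test of the interaction was planned before the data were examined, as were the splits of the samples; the weighing of technical explanations was chosen after the overall counts had been seen, and the comparison with probe sets matched for brightness, the bootstrap SE of medians and the splits that part same-numbered pairs after the values themselves.

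The change from untreated tissue to 5 days on NAA differed between the interfascicular region and the surrounding stem, by the test of the interaction itself, which does not separate NAA from culture, for 7 probe sets. BGLU33 differed by 7.26 (adjusted p = 0.0437; 5.66 without untreated stem replicate 1) and AT3G05620 by 3.52 (adjusted p = 0.00982); the unnamed probe sets 245725_at, 248590_at, 254168_at, 254515_at and 257093_at differed by 3.3, 3.72, 2.03, 5.36 and 1.45 (adjusted p = 0.00546, 0.0437, 0.021, 0.0437 and 0.021). All 7 passed with cyclic loess and quantile normalization, but 3 with the GAPDH covariate (AT3G05620, 245725_at and 257093_at). When only the compared groups were fitted 0 passed. Without the 3 narrow arrays, which leaves 1 untreated starch sheath array, the 7 differed by 1.72 to 8.51. BGLU33, AT3G05620 and the count depended on single arrays, with 1101 calls without untreated starch sheath replicate 1 and 1 without stem replicate 3 at 5 days. Of 100 splits of the arrays, 15 gave as many interaction calls and the highest other gave 4045, so chance is not excluded for the count, and a split with many times the real count points to a structure of the samples.

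At 2 days the interaction passed for 2 probe sets, 248236_at (-4.03) and 252971_at (-2.99), both with an adjusted p of 0.0152. The former lay at 8.67 in the stem on NAA against 4.54 untreated, and at 3.14 against 3.04 in the starch sheath. Both were lost with quantile normalization (0.23 and 0.126), with the GAPDH covariate (0.0507 for both) and when only the compared groups were fitted (0.266 for both), and passed with cyclic loess (0.0279 and 0.0156), and the count was 595 without untreated starch sheath replicate 1 and 0 without starch sheath replicate 2 or stem replicate 1 or 2 on NAA. Of 100 splits, 19 gave as many calls and the highest other gave 1000, and of 100 that part the same-numbered pairs on NAA 11 did (highest other 459), or 9 with the replicate block (highest other 86). These splits mix tissue and time in the same way, so chance is not excluded here either.

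A pattern to weigh is the excess of higher calls after 2 days on NAA against untreated starch sheath, 63.6% of 2672. If the narrow range of 2 untreated arrays were the source, quantile normalization should bring the share under 55%, and if not it should stay over 60%; it was 56.9%, which leaves this open. A change of scale on these arrays alone, with no change in the tissue, is argued against for the 1699 probe sets called higher. Of these 92.9% were also higher in the surrounding stem at 2 days, measured on other arrays with the narrow array left out. Among all probe sets 49% were, and among those matched for brightness 43.5%. A response of the tissue to culture and a difference in RNA quality stay open as untested explanations.

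A further pattern is the set of 53 probe sets higher in the cambium than in all 3 comparison groups at 5 days. A single cambium array could account for part of it: the lowest count with 1 left out was 16, without replicate 2, which lies between the bounds set for this test. Vascular bundle cells in the captured tissue would raise bundle genes, and the median difference between cambium and stem over 16 xylem, secondary wall and phloem genes was 0.07 (SE 0.065, 11 above 0), too wide an error to exclude it by its bound of 0.1. Dividing cells remain open as well, with a median of 0.19 over 37 division genes against medium (SE 0.043, 33 above 0). The count itself exceeded that of most splits: 3 of 100 gave as many, the real one included, and the highest other gave 1495. Because the splits also exchange treated and untreated arrays, they cannot exclude chance for a set defined by all 3 comparisons. That highest split points to a structure of the samples.

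For the 3 probe sets specific at 2 days, 4 of 100 splits gave as many and the highest other gave 1025, with the same sign of structure. Among 100 splits that part the 3 same-numbered pairs on NAA, as the real one does, 3 gave as many (highest other 23), and 2 of 100 gave as many as the 2 found with the replicate block (highest other 16), the latter without AT1G14130. These splits also exchange treated and untreated arrays, so they cannot exclude chance for a set defined by all 3 comparisons. The fixed gene list tests called 13 pairs, 10 of 100 splits called as many and the highest other called 18, so chance is not excluded. For the comparisons of 3 arrays against 3 the 10 splits are too few for a share under 0.05. The real count and the highest other were 87 and 1 (auxin at 2 days), 794 and 2 (auxin at 5 days), 56 and 29 (tissues at 2 days), 81 and 5 (tissues at 5 days), 460 and 3 (cambium against 2 days), 734 and 6 and 910 and 0 (stem at 2 and 5 days), with 1 split reaching the real count in each. For the tissues at 2 days the highest other of the 4 splits that part the pairs was 1, or 0 against 41 with the block, and the split with 29 joins pairs. Against the untreated starch sheath the real count and the highest other were 2672 and 1026 (2 days on NAA), 1124 and 491 and 1443 and 373 (medium at 2 and 5 days). For the untreated tissues they were 46 and 7874 and for the cambium against untreated 1952 and 6412, with 2 splits at or above the real count in each, which points to a structure of the samples.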

How the results depend on the processing

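The settings chosen after the data were seen are named above, and the others were planned. The fit without the 3 narrow arrays leaves 1 untreated starch sheath array. Of 86 named calls between cultured groups, 83 held with array weights, 82 at 2-fold, 80 with cyclic loess, 79 with quantile normalization, 80 with trend and robust prior, 79 with the GAPDH covariate, 74 with the replicate block, 80 without the narrow arrays, and 29 when only the compared groups were fitted; 35 held in every fit that left out 1 array. Of 116 named calls against or between untreated groups, 115, 108, 102, 112, 114, 40, 108, 90 and 43 held in the same order, and 72 in every fit that left out 1 array. The direction reversed for ATPC1 after 2 days on NAA against untreated (1.38 to -0.385 with cyclic loess and -0.098 with quantile normalization) and for MOL1 in the cambium against untreated (1.73 to -0.182 with the GAPDH covariate). The filter at 3.09, the median of all values, is not a measured background. Unless stated, the cause of a difference was not tested.

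Counts of calls that moved by over 1.5 times are given by setting. With array weights they were 495 and 3440 (auxin at 2 and 5 days), 4515, 179 and 651 (tissues at 0, 2 and 5 days), 6788 and 7048 (2 days on NAA and cambium against untreated), 1760 (cambium against 2 days), 2890 and 4312 (medium), 4704 and 4558 (stem), 1628 and 4391 (interactions), and 22 and 282 (specific sets). When only the compared groups were fitted, with fewer arrays to estimate the spread, they were 2 (auxin at 2 days), 0, 10 and 5 (tissues), 422 and 160 (2 days on NAA and cambium against untreated), 58 (cambium against 2 days), 154 and 227 (medium), 46 and 427 (stem), 0 and 0 (interactions), and 0 and 2 (specific sets). With the GAPDH covariate they were 1782 (auxin at 2 days), 10 and 129 (tissues at 0 and 5 days), 10 and 111 (2 days on NAA and cambium against untreated), 813 (cambium against 2 days), 359 and 327 (medium), 287 (stem at 2 days), 0 and 3 (interactions), and 0 and 11 (specific sets); the excess differs between treated and untreated groups, so the covariate removes part of that contrast. It also turned the share called higher from 57.7% to 38.3% (auxin at 5 days) at a count of 772, and from 59.3% to 28% (stem at 5 days) at 1248. Without the 3 narrow arrays they were 225 (auxin at 2 days), 149 (tissues at 0 days), 1028 (2 days on NAA against untreated), 830 (cambium against 2 days), 1445 (stem at 5 days), and 70 and 98 (interactions). Quantile normalization gave 184 (tissues at 0 days), 1765 (medium at 2 days), 0 and 34 (interactions), and cyclic loess 149 (auxin at 2 days), 1773 (2 days on NAA against untreated), 26 (interaction at 5 days) and 6 (specific at 2 days). At 2-fold 1614 were left after 2 days on NAA against untreated and 1 of the specific set at 2 days, and trend and robust prior gave 24 (interaction at 5 days). The counts of 0 stand beside unadjusted counts of 3146 (tissues at 0 days), 1401 and 2066 (interactions) in limma's fit of all arrays.

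With the replicate block the counts were 29 (tissues at 0 days), 2 (interaction at 5 days) and 41 (tissues at 2 days, where numbers pair arrays), or 26 with those 6 arrays alone. No other directly compared groups met the pairing rule. Untreated tissues correlated at 0.597, -0.082 and 0.584 for pairs 1 to 3, which leaves their pairing open. The block changed 12 of 86 and 8 of 116 named calls, 6 of the former in the paired comparison, and no other count by over 1.5 times. Of the fixed gene list tests 13 of 56 pairs were called (10 to 14 under other settings). Of the added lists it was 66 of 210 (50 to 72). An estimated correlation left 0.

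Leaving out 1 array in turn, with the remaining 2 of its group assumed to vary like the others, gave 10 to 101 and 406 to 717 calls (auxin at 2 and 5 days), 19 to 3938, 18 to 56 and 25 to 125 (tissues at 0, 2 and 5 days), 1099 to 8195 and 819 to 5798 (2 days on NAA and cambium against untreated), 197 to 474 (cambium against 2 days), 622 to 4376 and 518 to 5616 (medium), 339 to 1051 and 408 to 1067 (stem), 0 to 595 and 1 to 1101 (interactions), 0 to 5 and 13 to 87 (specific sets) and 9 to 17 (fixed gene list tests).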

Other observations

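The low oxygen list and its tests were chosen after 5 genes of this response had been seen among the largest rises; those 5 were left out of the list, and the bootstrap SE was added after the medians had been seen.

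Genes of the response to low oxygen were high at 5 days on NAA in both tissues. AT5G10040 lay at 7.69 ± 0.26 (SD, n = 3) in the cambium and 9.08 ± 0.73 in the surrounding stem, against 2.65 ± 0.23 on medium at 5 days and 2.47 ± 0.10 in the starch sheath after 2 days on NAA. AT4G10270 lay at 7.86 ± 0.46 and 7.65 ± 0.09 against 2.76 ± 0.06 and 3.27 ± 0.35, and AT1G33055, AT1G19530 and AT4G39675 were 3.59, 5.22 and 3.14 higher in the cambium than on medium. Of 15 other measured genes of the response, 7 rose in the cambium against medium, 0 fell and 8 did not pass, with 8 risen when adjusted over the list alone. AT4G24110, AT3G10040 (HRA1), AT3G27220, AT5G66985 and AT4G27450 rose by 2.87, 2.73, 2.70, 2.54 and 2.41. Against 2 days on NAA 7 rose, and in the stem against untreated tissue 8 rose; with the GAPDH excess as a covariate 5 rose against medium, 7 against 2 days and 4 in the stem. Camera gave adjusted p = 8.83e-17, 3.45e-16 and 1.52e-15 for these 3 comparisons, each with an adjusted p of 0.00292 with an estimated correlation, and 9.9e-11 (adjusted p = 0.0114 with an estimated correlation) for the cambium against untreated starch sheath. The list was not called between auxin and medium at 2 days (0.377), between cambium and stem at 5 days (0.714) or in the interaction at 5 days (0.902); AT5G10040 alone fell by 1.39 in the cambium relative to the stem (adjusted p = 0.0126).

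A single cambium array could be the source of the low oxygen pattern. The highest camera p with 1 cambium array left out was 2.97e-13, which argues against it. Picking a few genes for their size could also give such a pattern. The median change over the 15 other genes was 0.85, 14 of them above 0, with an SE of 0.622 that leaves this open by its bound. But against medium 7 rose, 0 fell, and camera with an estimated correlation gave adjusted p = 0.00292, which argues against picking for these 15. Oxygen in the tissue was not measured, and NAA and culture cannot be told apart for the stem. AT3G27220 is also among the genes specific to the cambium at 5 days.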
